A study of Mus musculus with 12 samples.

How the data were processed

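The data were RNA sequencing counts from B16F10 cells, a mouse melanoma line, grown in medium conditioned by bone-marrow-derived macrophages. The authors deposited 1 table of raw read counts, with 55487 Ensembl genes and 1 column for each of 12 libraries. The values were whole numbers with a different total in each library, so they were taken as counts that had not been normalised. HISAT2 2.0 and the mouse build mm10 are named in the submitters' processing notes, without a role or settings. The read counter, the annotation release, the strand setting and any filter are not given in the sources used here. Total RNA was extracted with Trizol and libraries were prepared with an Illumina mRNA protocol, per the labels' protocols. Without a stated strand, reads from a gene and an antisense neighbour cannot be told apart, and reads that match several members of a gene family could have been divided or dropped. Values of close relatives such as the Gbp, Tgtp, Iigp, Ifit and H2 genes are therefore uncertain.

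Each column name matched the title of 1 sample, and the groups and replicate numbers came from the sample labels. A misspelt title of TAM replicate 2 was settled by its treatment label. Gene symbols were found for 55141 of the identifiers, and 55227 were present in GENCODE release M21, which uses GRCm38, the assembly also called mm10. Coordinates are 1-based positions from that release and exon lengths are the merged exons of each gene.

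Totals lay between 15916756 and 20863973 counts per library. A floor of 3 counts, summed over the libraries of a group, stood for a group without any count, and ratios against groups with 1 to 3 counts carry an exact conditional binomial interval at 95% confidence. These floors and intervals cover counting error only. Reads without molecular identifiers are not independent molecules.

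Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and all 12 libraries entered 1 quasi-likelihood fit with robust estimation and a mean per group, so that all groups shared 1 estimate of the spread. Each of 6 comparisons between groups was tested with the quasi-likelihood test and adjusted by Benjamini-Hochberg over the 14591 genes tested. A gene was called changed at an adjusted p under 0.05. Log2 fold changes are given with approximate standard errors (SE), the absolute change divided by the square root of the F statistic of its test. Levels are given as CPM, counts relative to library totals after TMM scaling, with the standard deviation (SD) of 3 libraries. Macrophage marker sums, and the values of Coro1a, Lyz2 and Fcer1g in M0 replicate 1, were taken without TMM scaling. Every adjusted p for a gene comes from this test unless another tool is named.

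The comparisons, the tests, 25 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered immune and inflammatory responses, melanocyte and mesenchymal genes, signalling targets, cell cycle, metabolism, stress responses, cell death and markers of other cell types, 534 entries of 515 distinct genes in all. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The number of members called is given over all genes tested and adjusted over the list alone. Named genes were the 10 with the largest rise and the 10 with the largest fall in each comparison with M0, or 5 each in the other comparisons. They had to pass the test, reach a mean of 1 CPM over the 6 libraries compared and show no overlap between the groups, and predicted genes and pseudogenes were left out. Up to 4 members per list with the smallest adjusted p were added, with Mitf, Tyr, Pmel, Irf1, Cd274, Ptprc, Cd68, Csf1r and Lyz2 as checks. Some genes that the rule names are not reported here.

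Similarity between responses was measured as the correlation and the covariance of log2 fold changes across genes. Because M1, M2 and TAM share the M0 libraries, 20 simulations with no effect were run, once with simulated M0 libraries and once with the M0 libraries as deposited. Covariances were also taken with M0 replicate 2 as the control of 1 response and M0 replicate 3 as that of the other, which was added after the data had been seen. The counting, testing and list steps were tested on simulated counts for M2 versus M0 with 50 genes changed at each of 4 fold sizes. With the spread of all 12 libraries, 16% of genes changed 1.5-fold and 64% of genes changed 2-fold were recovered, over 13778 genes tested. With the spread estimated without M0 replicate 1, 78% and 98% were recovered over 13752 genes. With M0 replicate 1 as deposited they were 34% and 60% over 13801 genes. Every setting held 3 libraries per group. The shares of 78% and 98% therefore do not measure recovery in the fit without M0 replicate 1, which had fewer M0 libraries. A cell cycle list raised 1.2-fold was called in all 3 settings, and camera also called 1, 2 and 4 of the lists that had not been shifted.

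The alternatives planned were RLE size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, the 20 most abundant genes left out, a test against a fold of 1.5, a fit of only the libraries compared, and each library left out in turn. Another 2 kinds were added after the data had been seen: M0 replicate 1 left out of comparisons that do not use M0, and offsets that removed each library's trend with exon length. A fit meant for normalised values was not run because the table held counts.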

Results

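B16F10 cells were sequenced after 24 h in medium taken from macrophages that had themselves been treated for 24 h. The macrophage treatment defined 4 groups of 3 libraries. M0 macrophages received control medium, M1 macrophages 20 ng/ml of a cytokine written as INF-γ in the labels and read here as interferon gamma, M2 macrophages 20 ng/ml of interleukin-4, and the macrophages of the group called TAM here 75% medium conditioned by B16F10 cells, after the series' term for tumour-associated macrophages. The labels do not say whether cytokine or tumour medium was removed before the macrophage medium was collected. Nor do they say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Totals ran from 15916756 to 20863973 counts per library, and 14591 genes were tested.

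Markers of other cell types were near the detection limit in the melanoma libraries. Of 23 macrophage markers 5 were abundant enough to be tested, of 12 macrophage polarisation markers 2, of 10 neutrophil markers 0, of 12 lymphocyte markers 1, and of 12 fibroblast and endothelial markers 5. Ptprc and Csf1r, pan-leukocyte and macrophage receptor genes, were below the filter. The 23 macrophage markers together summed to between 3.94 and 8.43 CPM per library, taken without TMM scaling. Cd68 stood at 3.01 ± 0.644 CPM (SD, n = 3) in M0, 4.47 ± 0.414 in M1 and 1.51 ± 0.458 in TAM, and Lyz2 at 0.935 ± 0.405, 0.768 ± 0.192 and 1.06 ± 0.111 CPM. These low levels differed between groups. The sum was 3.94 to 4.67 CPM in TAM and 5.27 to 8.08 CPM in M0. In TAM versus M0, 3 of the 5 tested macrophage markers were lower, Cd68 among them (adjusted p = 0.00533), and 0 higher (3 adjusted over the list alone, median −0.99, camera adjusted p = 0.309, fry adjusted p = 0.0109), or 2 lower without M0 replicate 1. In TAM versus M1 2 were lower and in TAM versus M2 1 (2 and 1 adjusted over the list alone, camera adjusted p = 0.217 and 0.329, fry adjusted p = 0.000744 and 0.0184).

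M0 replicate 1 stood apart from all other libraries. Its log2 CPM correlated with the other M0 libraries at r = 0.945 and 0.948 across genes, against 0.992 to 0.993 for all other pairs within a group. Ribosomal protein genes took 7.11% of its counts against 3.21% to 3.75% elsewhere, and its count-weighted mean exon length was 4545 bp against 5817 to 6091 bp. The common dispersion was 0.0324 with all 12 libraries and 0.00166 without this one. All 12 libraries were kept in the fit as designed, and counts without M0 replicate 1, over 14968 genes, are given beside each comparison because they differed by over 1.5 times in most.

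M1 versus M0 showed what medium of interferon-treated macrophages did to the melanoma cells relative to medium of untreated macrophages. The design does not separate products of these macrophages from interferon gamma left in the medium, and this holds for every interferon, MHC and checkpoint result with M1. Interferon-inducible genes rose. All 40 tested members of the interferon response list rose (40 adjusted over the list alone), with a median log2 change of 7.68, and camera gave an adjusted p of 2.21e-118 (adjusted p = 3.32e-05 with an estimated correlation). Gbp2, a guanylate-binding GTPase of cell-autonomous defence (chromosome 3, 142620602 to 142638008, plus strand, mm10), reached 4067 ± 133 CPM (SD, n = 3) in M1 against 1.26 ± 0.326 in M0, a log2 change of 11.66 ± 0.20 (SE, adjusted p = 4.1e-11). Cxcl10, a chemokine that attracts activated T cells (chromosome 5, 92346638 to 92348889, minus strand), reached 2041 ± 33.3 against 10.5 ± 0.915 CPM, a log2 change of 7.60 ± 0.13 (adjusted p = 4.1e-11). The GTPase genes Irgm1 and Irgm2 rose by 7.12 ± 0.16 and 9.36 ± 0.22 on the log2 scale. Irf1, a transcription factor of the interferon pathway, rose by 5.59 ± 0.16 (adjusted p = 1.61e-09). The 10 largest rises were all in genes with no count in M0, so that only bounds against a floor of 3 counts over the group can be given. Iigp1 was at least 32500-fold higher at 1783 ± 85.4 CPM, Gbp4 at least 23200-fold, Tgtp2 at least 18700-fold, Tgtp1 at least 10800-fold, Apol6 at least 8950-fold, Cxcl9 at least 7290-fold, Gbp10 at least 6460-fold, Serpina3f at least 2200-fold, Ifi204 at least 1910-fold and Ifi44 at least 1500-fold.

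Antigen presentation genes rose with them. All 18 tested genes of MHC class I presentation rose (18 adjusted over the list alone, median log2 change 5.10, camera adjusted p = 1.62e-50). B2m, the light chain of class I molecules (chromosome 2, 122147686 to 122153083), went from 173.5 ± 23.5 to 2833 ± 97.9 CPM, a log2 change of 4.03 ± 0.11 (adjusted p = 1.19e-09), and Tap1, a subunit of the peptide transporter, from 1.58 ± 0.595 to 543 ± 19.7 CPM. All 7 tested class II genes rose (7 adjusted over the list alone, camera adjusted p = 8.55e-15), by a median of 7.99, or 6.32 with genes absent from M0 at their bound. They included Ciita, the class II transactivator, at 24.8 ± 3.77 CPM in M1, and Cd74, the invariant chain, at 72.8 ± 2.44. Of 11 tested immune checkpoint and suppression genes 8 rose and 0 fell (8 adjusted over the list alone, median 2.26, camera adjusted p = 5.12e-12). Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095), rose from 3.49 ± 1.37 to 127.9 ± 1.24 CPM, a log2 change of 5.21 ± 0.23 (adjusted p = 3.33e-08), and Cd47 rose by 2.26 ± 0.10.

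Inflammatory and death genes also rose. In the NF-kB and inflammatory list 15 of 17 tested genes rose (15 adjusted over the list alone, median 1.61, camera adjusted p = 8.55e-15), among them the chemokine gene Ccl5, by 5.87 ± 0.28, and Csf1, the macrophage growth factor gene, by 2.73 ± 0.12. Of 13 STAT3 targets 10 rose (10 adjusted over the list alone, median 1.41, camera adjusted p = 1.66e-12), with Stat3 itself higher by 2.27 ± 0.13. Of 18 genes of apoptosis and necroptosis 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.87, camera adjusted p = 1.11e-13), including Casp4 by 6.19 ± 0.24, Mlkl, the executor of necroptosis, by 2.36 ± 0.10 and Bid by 1.68 ± 0.09. Of 17 immediate early genes 7 rose and 2 fell (7 and 3 adjusted over the list alone, median 0.36, camera adjusted p = 0.00401).

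Pigment and proliferation genes moved down in M1. Of 19 melanocyte genes 12 fell and 0 rose (12 adjusted over the list alone, median −0.91, camera adjusted p = 9.09e-09). Tyr, the rate-limiting enzyme of melanin synthesis, changed by −1.15 ± 0.16 (adjusted p = 0.000418), Pmel, a melanosome structural protein, by −1.24 ± 0.17 (adjusted p = 0.000371) and Trpm1 by −2.16 ± 0.13. Pmel stood at 7782 CPM in M0 replicate 1 and 4682 in the other M0 libraries, and without that replicate it changed by −0.92. Mitf, the melanocyte master regulator, stood at 351.7 ± 55.9 CPM in M1 and 457.3 ± 203 in M0, with an adjusted p of 0.342 over all 12 libraries and 0.00163 without M0 replicate 1. Of 36 cell cycle genes 23 fell and 0 rose (25 adjusted over the list alone, median −0.45, camera adjusted p = 7.39e-08), including Cdk2 by −1.08 ± 0.10, and the estimated-correlation p of 0.00463 became 0.137 without M0 replicate 1. Of 33 glycolysis and hypoxia genes 17 fell and 2 rose (19 and 2 adjusted over the list alone, camera adjusted p = 0.000271, adjusted p = 0.199 with an estimated correlation). Of 31 oxidative phosphorylation genes 6 fell and 0 rose (5 adjusted over the list alone, camera adjusted p = 0.000271, adjusted p = 0.513 with an estimated correlation). Of 12 mitochondrially encoded genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.00223). The mesenchymal and invasion list was mixed, with 7 of 19 genes higher and 3 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.00895, adjusted p = 0.106 with an estimated correlation). In it Axl and Ngfr, markers of dedifferentiated melanoma cells, rose by 1.98 ± 0.12 and 3.79 ± 0.22, and Fn1, encoding fibronectin, by 2.96 ± 0.24, while Col1a2 changed by −2.81 ± 0.39. The stress-response and cholesterol lists, with camera adjusted p of 0.709 and 0.42, did not pass in M1. Leaving out M0 replicate 1 moved some of these lists, to 16 melanocyte genes lower and 2 higher, 12 mesenchymal genes higher and 5 lower, and 20 glycolysis genes lower and 6 higher (median −0.29). It also left 15 of 19 death genes higher and 2 lower, and 13 oxidative phosphorylation genes lower and 1 higher (median −0.11, camera adjusted p = 0.0671). The largest falls were in genes of low abundance such as Abca12, by −3.43 ± 0.34, and Azgp1, by −2.90 ± 0.35. In all, 3744 genes were called, 1777 higher and 1967 lower, of which 966 and 494 changed at least 2-fold. Which direction held more genes depended on the settings, with 1871 higher and 1781 lower by RLE size factors, 1628 and 2266 by upper-quartile factors and 1720 and 1205 with no filter. Without M0 replicate 1 the count was 7056, 3630 higher and 3426 lower, which held 3619 of the 3744 in the same direction, and without M1 replicate 1 or 3 it was 2287 or 2351.

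M2 versus M0 asked the same of medium from interleukin-4-treated macrophages. No gene passed edgeR's quasi-likelihood test with all 12 libraries, so 0 genes were called, with 980 genes at an unadjusted p under 0.05. DESeq2 called 4 genes and limma-voom 0. The 4, named after their values were seen, were Stat3, Masp1 and Gnb4, higher by 0.81, 0.51 and 0.44 on the log2 scale, and the predicted gene Gm10705, lower with a change of −1.31. Their adjusted p values in DESeq2 were 8.57e-05, 0.00602, 0.00733 and 0.000437, and in edgeR 0.481, 0.535, 0.535 and 0.159. Of 7 tested members of the IL-4 and STAT6 response list 0 were called (0 adjusted over the list alone, median 0.03, camera adjusted p = 0.62). Among 13 STAT3 targets, a list that holds Stat3 itself, 0 were called over all genes and 3 were higher adjusted over the list alone (median 0.25, camera adjusted p = 0.00132, adjusted p = 0.0787 with an estimated correlation), and the camera call was lost without M0 replicate 3 (adjusted p = 0.0944). Among 31 oxidative phosphorylation genes 0 were called on either basis (median −0.46, camera adjusted p = 1.16e-08, adjusted p = 0.673 with an estimated correlation), and the median was −0.06 without M0 replicate 1. The interferon, melanocyte, cell cycle and cholesterol lists did not pass camera, with adjusted p values of 0.321, 0.255, 0.48 and 0.255.

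Leaving out M0 replicate 1 changed this comparison, with 51 genes called, 31 higher and 20 lower. The genes given here were chosen after their values were seen. The largest rises were in Il12rb1, an interleukin-12 receptor gene, by 1.54 ± 0.32, Irgm2 by 1.24 ± 0.21 and Fos by 1.08 ± 0.24. In the same fit M1 medium raised Il12rb1 and Irgm2 by 7.26 and 9.67. With all 12 libraries the changes of Il12rb1, Irgm2 and Fos in M2 were 0.89, 0.96 and 1.17 (adjusted p = 0.535 for each), so the order depended on M0 replicate 1, which held 1.62 CPM of Il12rb1 against 1.74 in M2 and 0.585 in the other M0 libraries. Stat3, a cytokine-activated transcription factor (chromosome 11, 100885098 to 100939540, minus strand), stood at 166.6 ± 8.13 CPM in M2 (SD, n = 3) and 104.9 in the other M0 libraries, a log2 change of 0.67 ± 0.05 (adjusted p = 6.76e-14). Socs3, a feedback inhibitor induced by STAT3, was higher by 0.51 ± 0.11, Bcl6 by 0.66 ± 0.16 and Gfap by 0.70 ± 0.14, against 0.29, 0.73 and 0.52 with all 12 libraries (adjusted p = 0.535 for each). M0 replicate 1 held 15.4 CPM of Socs3, above the 14.8 of M2. The melanocyte genes Trpm1, Pmel and Tyrp1 were lower, with changes of −0.43 ± 0.09, −0.17 ± 0.04 and −0.15 ± 0.04. With all 12 libraries they changed by −0.50, −0.47 and 0.02 (adjusted p = 0.535, 0.535 and 0.924). Of the 51 genes 3 rose and 1 fell by at least 2-fold. Camera called 13 lists in this fit, among them the interferon, melanocyte and cell cycle lists (adjusted p = 0.0223, 4.87e-08 and 0.000144), for which the adjusted p was 0.518, 0.133 and 0.37 with an estimated correlation. The STAT3 list alone passed with an estimated correlation (adjusted p = 0.00332), with Stat3 and Socs3 as its 2 called members. In simulated M2 versus M0 data 16% of genes changed 1.5-fold were recovered with the spread of all 12 libraries (13778 genes) and 34% with M0 replicate 1 as deposited (13801 genes). Most changes of that size would have been missed with this library included.

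TAM versus M0 showed what medium of tumour-conditioned macrophages did relative to medium of untreated macrophages. The whole cholesterol and lipid synthesis list fell, with 28 of 28 genes lower (28 adjusted over the list alone, median −2.06, camera adjusted p = 2.09e-22). Dhcr7, which catalyses the last step of 1 route of cholesterol synthesis (chromosome 7, 143823145 to 143848410), went from 180.8 ± 16.1 CPM (SD, n = 3) to 26.4 ± 3.16, a log2 change of −2.78 ± 0.11 (SE, adjusted p = 2.92e-08). Nsdhl, another enzyme of the pathway (chromosome X, 72918557 to 72958514), went from 72.7 ± 5.33 to 15.0 ± 0.983 CPM, a change of −2.27 ± 0.09 (adjusted p = 3.24e-08). Proliferation genes fell too. Of 36 cell cycle genes 34 fell and 1 rose (34 and 1 adjusted over the list alone, median −1.32, camera adjusted p = 2.3e-20), with the mitotic kinases Aurkb and Plk1 at −2.69 ± 0.09 and −2.23 ± 0.10, the replication helicase gene Mcm6 at −2.16 ± 0.08 and Cdk2 at −2.14 ± 0.10.

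Stress-response genes rose in TAM. Of 29 genes of the integrated stress and unfolded protein response 22 rose and 3 fell (22 and 3 adjusted over the list alone, median 1.76, camera adjusted p = 3.7e-11, adjusted p = 0.0693 with an estimated correlation, 0.00638 without M0 replicate 1). Ppp1r15a, the GADD34 phosphatase subunit that reverses translational arrest (chromosome 7, 45522916 to 45526268, minus strand), went from 18.1 ± 3.25 to 519.8 ± 11.4 CPM, a log2 change of 4.85 ± 0.16 (adjusted p = 1.33e-08). Atf3 rose by 4.16 ± 0.19, Cth, an enzyme of cysteine synthesis, by 3.89 ± 0.14 and Vldlr by 3.80 ± 0.17. Fgf21, a secreted stress hormone, had 2861 counts in TAM and 2 in M0, a ratio of 1330 with a 95% counting interval from 367 to 11000. Of 14 p53 targets 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 1.59, camera adjusted p = 2.96e-08), with Gdf15, a secreted growth differentiation factor, higher by 6.96 ± 0.44, Plk2 by 3.64 ± 0.18, Btg2 by 2.85 ± 0.14 and Mdm2 by 2.03 ± 0.15. In the oxidative stress list 11 of 21 rose and 4 fell (11 and 5 adjusted over the list alone, median 0.59, camera adjusted p = 0.00815, adjusted p = 0.456 with an estimated correlation). Hmox1, heme oxygenase 1, rose by 3.87 ± 0.17, Txnrd1 by 1.84 ± 0.13, and Sqstm1 from 1517 ± 465 to 8384 ± 137 CPM.

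Signalling targets rose in TAM as well. Of 16 TGF-beta response genes 11 rose and 1 fell (11 and 2 adjusted over the list alone, median 1.65, camera adjusted p = 1.22e-05), with Ccn1, encoding a matrix-associated signalling protein, higher by 4.77 ± 0.20, Tgif1 by 2.59 ± 0.10 and Id3 by 2.52 ± 0.19. Of 17 immediate early genes 13 rose and 1 fell (13 and 2 adjusted over the list alone, median 1.86, camera adjusted p = 3.08e-10), including Klf4 by 3.41 ± 0.20 and Jun by 1.96 ± 0.09. Of 13 STAT3 targets 11 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.34, camera adjusted p = 1.22e-05), and of 17 NF-kB and inflammatory genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.04, camera adjusted p = 1.22e-05). Lif, encoding leukaemia inhibitory factor, rose by 6.28 ± 0.35. The interferon response list was partly raised, with 16 of 40 higher and 5 lower (16 and 5 adjusted over the list alone, median 0.82, or 0.50 with bounds, camera adjusted p = 0.00815, adjusted p = 0.204 with an estimated correlation). Cxcl10 rose to 188.3 ± 5.59 CPM, a change of 4.16 ± 0.11 (adjusted p = 5.71e-09), while Irf1 changed by −0.41 ± 0.14 (adjusted p = 0.0296). Irf1 did not pass without TAM replicate 1, 2 or 3 (adjusted p = 0.0773, 0.0804 and 0.0569). The MHC class I list had 5 of 18 genes higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.265), or 12 higher and 2 lower without M0 replicate 1. The class II list had 1 of 7 higher, Cd74 by 5.64 ± 0.51, and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.449). Of 11 checkpoint genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.91, camera adjusted p = 0.0395, adjusted p = 0.103 with an estimated correlation, 0.0239 without M0 replicate 1), with Cd274 higher by 0.91 ± 0.22 (adjusted p = 0.00532).

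Melanocyte genes fell in TAM, 14 of 19 lower and 1 higher (15 and 1 adjusted over the list alone, median −1.19, camera adjusted p = 1e-05). Mitf (chromosome 6, 97807052 to 98021349) went to 110.3 ± 2.41 CPM, a log2 change of −2.05 ± 0.29 (adjusted p = 0.000177), Pmel changed by −1.85 ± 0.17, Mc1r, the melanocortin receptor, by −2.35 ± 0.13 and Tyr by −0.92 ± 0.16. Without M0 replicate 1 the change of Pmel was −1.57. Of 33 glycolysis and hypoxia genes 22 fell and 7 rose (22 and 7 adjusted over the list alone, median −1.17, camera adjusted p = 0.00106, adjusted p = 0.268 with an estimated correlation). Ldha, lactate dehydrogenase A, changed by −2.13 ± 0.16, whereas Vegfa and Eno2 rose by 2.62 ± 0.19 and 2.50 ± 0.17. Of 31 oxidative phosphorylation genes 20 fell and 0 rose (20 adjusted over the list alone, median −0.71, camera adjusted p = 0.000608, adjusted p = 0.508 with an estimated correlation). Their list did not pass camera in TAM versus M1 (7 lower and 0 higher, median −0.14, adjusted p = 0.431). Nor did it pass in TAM versus M2 (12 lower and 2 higher, median −0.22, camera adjusted p = 0.115). In the fit without M0 replicate 1 20 of them fell and 6 rose (median −0.38). That fit also had 3 melanocyte genes higher, and 2 NF-kB and inflammatory and 3 TGF-beta genes lower. The mesenchymal and invasion list had 8 of 19 genes higher and 5 lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.121), with Axl at 2.30 ± 0.12, Ngfr at 4.14 ± 0.22 and Vim, encoding vimentin, at −1.37 ± 0.09. Beyond the lists, Hrk, a BH3-only death gene, was at least 76.0-fold and Emp2 at least 42.9-fold higher. The largest falls included Gamt, the last enzyme of creatine synthesis, at −5.38 ± 0.35, Map2k6, a kinase upstream of p38, at −5.07 ± 0.22 and Mxd3 at −5.00 ± 0.34. The test called 7372 genes, 3398 higher and 3974 lower, of which 1672 and 1774 changed at least 2-fold. Without M0 replicate 1 the count was 9983, and 7145 of the 7372 were called again in the same direction.

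**Figure D1:**
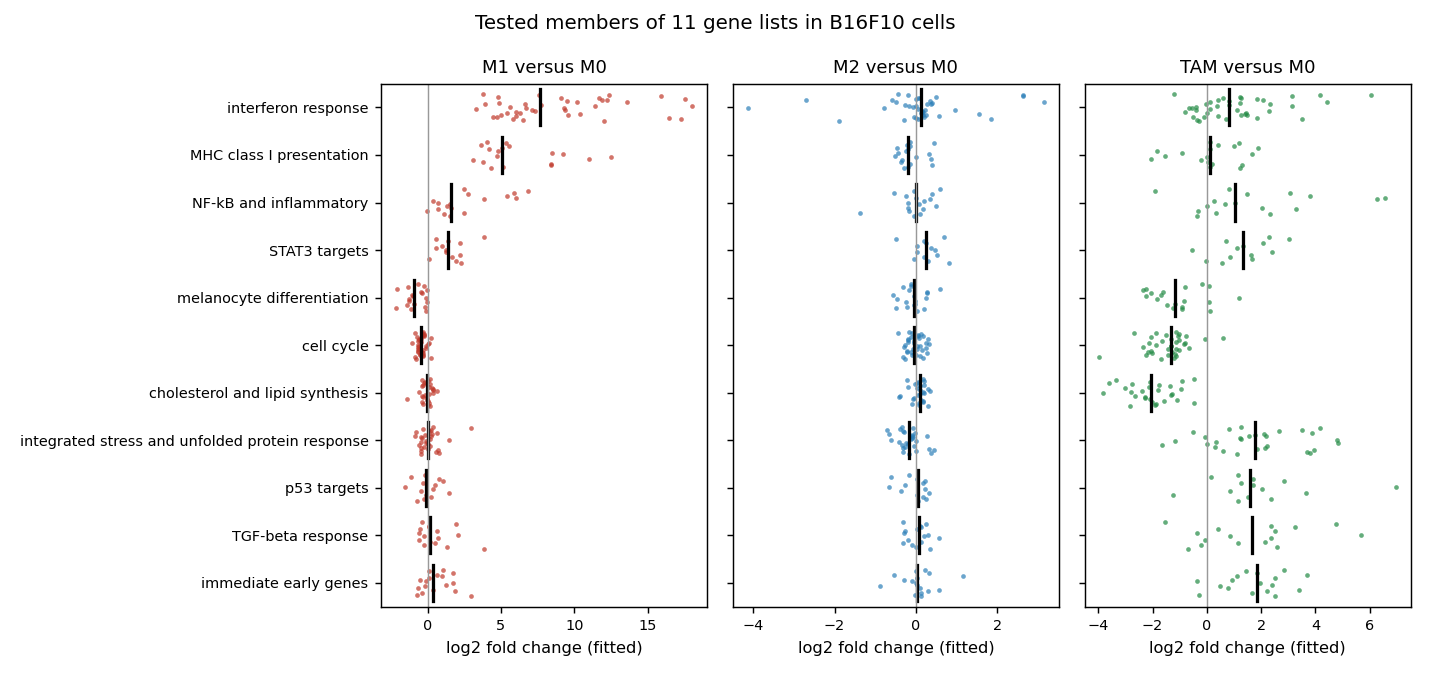
Fitted log2 fold changes against M0 (x axis, a different scale in each panel) of the tested members of 11 gene lists (y axis) in M1, M2 and TAM. Each point is a gene, its place within a band has no meaning, and black bars are list medians, such as 7.68 for the interferon list in M1 and −2.06 for the cholesterol list in TAM. Fitted values of genes without counts in a group are not bounds.

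**Figure D2:**
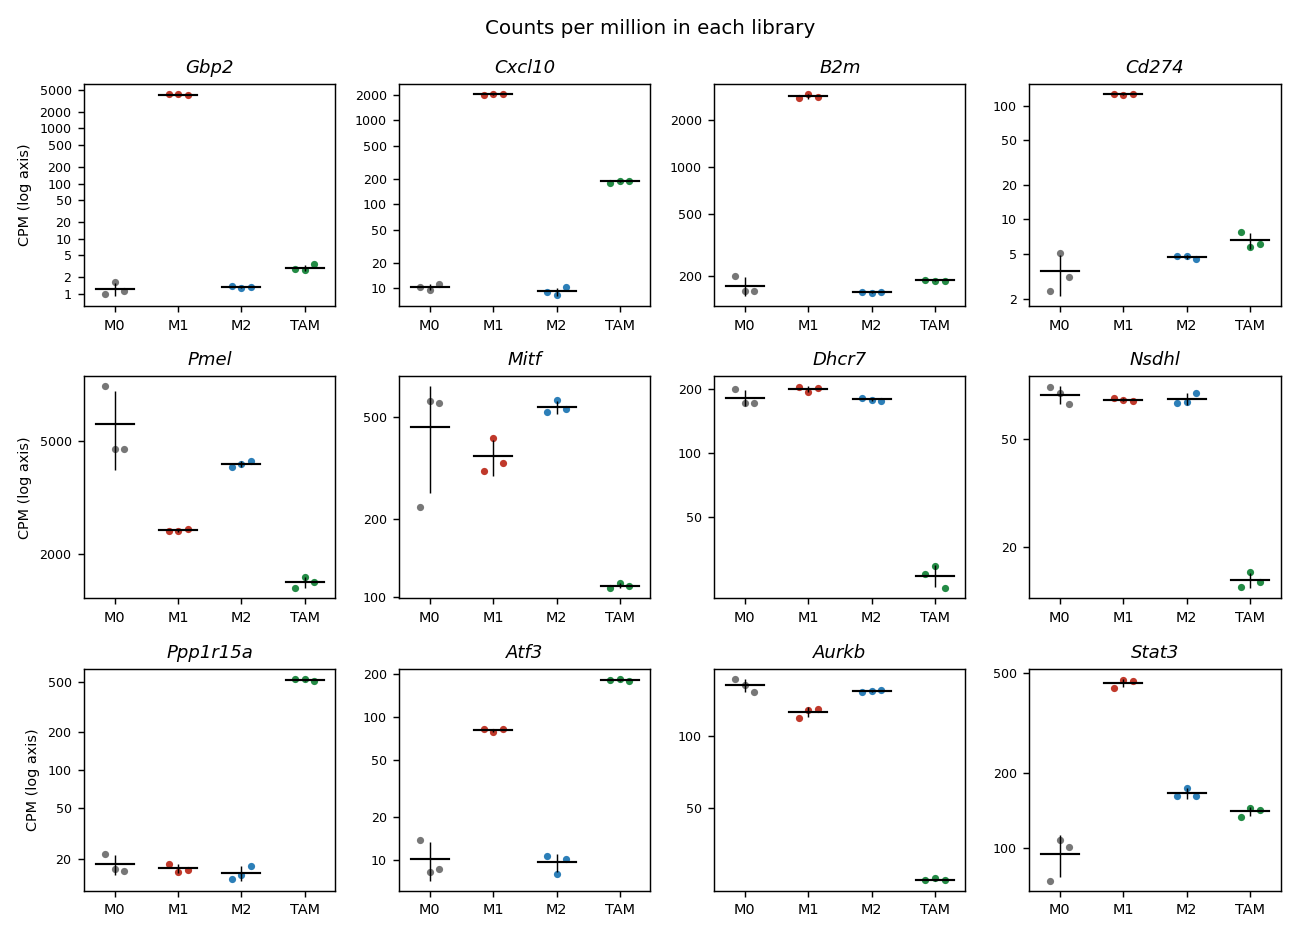
CPM on log axes for 12 genes in each of 12 libraries, grouped by the macrophage medium on the x axis. Points are libraries, horizontal bars group means and vertical bars 1 SD (n = 3). Gbp2 and B2m stand highest in M1, Ppp1r15a stands at 519.8 CPM in TAM and Dhcr7 at 26.4 CPM.

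TAM versus M1 set the tumour-conditioned against the interferon-treated macrophage medium. Interferon and antigen presentation genes were far lower in TAM. All 40 interferon genes were lower (40 adjusted over the list alone, median −7.08, camera adjusted p = 5.44e-66), as were all 18 class I genes (18 adjusted over the list alone, median −4.77, camera adjusted p = 2.86e-28) and all 7 class II genes (7 adjusted over the list alone, median −7.45, or −5.69 with bounds, camera adjusted p = 4.05e-09). Gbp2 differed by −10.41 ± 0.19 (SE, adjusted p = 1.42e-10) and Irf1 by −6.00 ± 0.16 (adjusted p = 1.1e-09). Gbp4 had 1 count in TAM and 71816 in M1, a ratio of 75100 with a 95% counting interval from 13500 to 2960000. Of 18 apoptosis and necroptosis genes 11 were lower and 1 higher (11 and 1 adjusted over the list alone, median −0.93, camera adjusted p = 1.95e-06), with Casp12, which had no count in TAM, at least 771-fold lower. Of 11 checkpoint genes 6 were lower and 4 higher (6 and 4 adjusted over the list alone, median −2.16, camera adjusted p = 0.00245), with Cd274 at −4.29 ± 0.22.

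The stress, sterol and proliferation groups also separated TAM from M1. Of 29 stress-response genes 25 were higher and 2 lower (25 and 2 adjusted over the list alone, median 1.79, camera adjusted p = 2.07e-13), with Ppp1r15a at 4.96 ± 0.16 (adjusted p = 2.53e-09) and Herpud1 at 2.41 ± 0.10. Fgf21 had 2861 counts against 3, a ratio of 912 with a 95% counting interval from 312 to 4430. Of 28 cholesterol genes 27 were lower (28 adjusted over the list alone, median −1.92, camera adjusted p = 5.87e-22), with Dhcr7 at −2.91 ± 0.11, and of 36 cell cycle genes 33 were lower (33 lower and 1 higher adjusted over the list alone, median −0.86, camera adjusted p = 6.15e-13), with the thymidine kinase gene Tk1 at −3.07 ± 0.20. Of 14 p53 targets 13 were higher and 1 lower (13 and 1 adjusted over the list alone, median 1.48, camera adjusted p = 5.42e-09), of 16 TGF-beta genes 12 higher and 2 lower (12 and 2 adjusted over the list alone, median 1.15, camera adjusted p = 9.62e-06), and of 17 immediate early genes 11 higher and 1 lower (11 and 1 adjusted over the list alone, median 1.15, camera adjusted p = 4.2e-06), among them Myc at 2.05 ± 0.10. In the oxidative stress list 11 of 21 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.000157, adjusted p = 0.29 with an estimated correlation), with Slc7a11, the cystine transporter, at 3.25 ± 0.33. Of 5 fibroblast and endothelial markers 4 were higher (4 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.0536 with an estimated correlation, and camera adjusted p = 0.271 without M0 replicate 1), with Vwf, encoding von Willebrand factor, at a log2 change of 1.39 ± 0.26. Mitf was lower by a log2 change of −1.67 ± 0.29. The melanocyte list split, 6 of 19 higher and 7 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.879). In total 6279 genes were called, 2886 higher and 3393 lower, of which 1156 and 1580 changed at least 2-fold, while upper-quartile factors gave 3110 higher and 3103 lower. M0 replicate 1 enters this comparison through the gene filter, the scaling and the shared spread. Without it 10489 were called, 6264 of the 6279 among them, with 2 cell cycle genes higher and 4 oxidative stress genes lower. The median of all genes tested moved from −0.000399 to −0.0393.

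TAM versus M2 repeated most of the TAM pattern without using any M0 level. All 28 cholesterol genes were lower (28 adjusted over the list alone, median −1.96, camera adjusted p = 1.15e-26), with Dhcr7 at −2.75 ± 0.11 (SE, adjusted p = 3.52e-08) and Cyp51 at −2.17 ± 0.09 (adjusted p = 3.52e-08). Of 36 cell cycle genes 34 were lower and 1 higher (34 and 1 adjusted over the list alone, median −1.35, camera adjusted p = 6.25e-23). Of 29 stress-response genes 24 were higher and 2 lower (24 and 2 adjusted over the list alone, median 1.65, camera adjusted p = 6.47e-14), with Ppp1r15a at 5.08 ± 0.16 (adjusted p = 1.19e-08) and Atf3 at 4.24 ± 0.20. Of 14 p53 targets 13 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 3.48e-09), of 16 TGF-beta genes 11 and 1 (11 and 2 adjusted over the list alone, camera adjusted p = 4.16e-06), and of 17 immediate early genes 13 and 1 (13 and 1 adjusted over the list alone, camera adjusted p = 1.14e-10). Melanocyte genes were mostly lower, 14 of 19 with 3 higher (14 and 3 adjusted over the list alone, median −1.10, camera adjusted p = 1.52e-05), and Mitf differed by −2.31 ± 0.30 (adjusted p = 8.83e-05). Of 13 STAT3 targets 9 were higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.000561), and of 17 NF-kB and inflammatory genes 10 higher and 0 lower (10 adjusted over the list alone, camera adjusted p = 1.52e-05). A further 4 lists passed camera and not the estimated correlation. These were the interferon list with 14 of 40 higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.0154, adjusted p = 0.26 with an estimated correlation, and 15 and 7 with camera adjusted p = 0.0702 without M0 replicate 1), the checkpoint list with 5 of 11 higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.0927 with an estimated correlation, 0.0325 without M0 replicate 1), the glycolysis and hypoxia list with 23 of 33 lower and 7 higher (23 and 7 adjusted over the list alone, camera adjusted p = 0.000921, adjusted p = 0.27 with an estimated correlation) and the oxidative stress list with 11 of 21 higher and 4 lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.000921, adjusted p = 0.34 with an estimated correlation). Cox6a2, a muscle-type subunit of cytochrome oxidase, had no count in M2 and was at least 295-fold higher in TAM, and Ackr3, a scavenging chemokine receptor, differed by −4.76 ± 0.59. The test called 6309 genes, 3016 higher and 3293 lower, of which 1374 and 1425 changed at least 2-fold. Without M0 replicate 1 it called 10407, including 6300 of the 6309, with 3 STAT3 targets, 2 NF-kB and inflammatory and 2 TGF-beta genes lower.

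M1 versus M2 compared the media of macrophages given the 2 cytokines. All 40 interferon genes (median 7.91, camera adjusted p = 2.17e-142), all 18 class I genes (median 5.28, camera adjusted p = 8.37e-61) and all 7 class II genes (median 9.24, or 6.40 with bounds, camera adjusted p = 2.48e-18) were higher in M1, with 40, 18 and 7 adjusted over the list alone. Gbp2 was higher by 11.55 ± 0.20 (SE, adjusted p = 4.18e-11), Cxcl10 by 7.79 ± 0.13 (adjusted p = 4.18e-11) and Cd274 by 4.78 ± 0.23 (adjusted p = 5.23e-08). Of 11 checkpoint genes 9 were higher (9 adjusted over the list alone, camera adjusted p = 9.78e-15), of 17 NF-kB and inflammatory genes 13 (14 adjusted over the list alone, camera adjusted p = 3.31e-17), of 13 STAT3 targets 10 (11 adjusted over the list alone, camera adjusted p = 2.87e-12) and of 18 death genes 10, with 1 lower (13 and 2 adjusted over the list alone, camera adjusted p = 6.53e-15). Socs1, a feedback inhibitor of cytokine signalling in the IL-4 and STAT6 list, was higher by 5.48 ± 0.30 in M1 and Socs2 lower, with a change of −2.48 ± 0.22. That list had 3 of 7 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0466, adjusted p = 0.109 with an estimated correlation). It shares 5 of its 15 members with other lists, and Socs1 is also in the interferon list. Melanocyte genes were lower in M1, 10 of 19 with 0 higher (11 adjusted over the list alone, median −0.71, camera adjusted p = 5.11e-09), with Tyr at −1.36 ± 0.16 (adjusted p = 0.00014), as were 17 of 36 cell cycle genes (22 adjusted over the list alone, median −0.42, camera adjusted p = 1.72e-08). Of 17 immediate early genes 6 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.0105). The mesenchymal list had 6 of 19 higher and 4 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.0466, adjusted p = 0.175 with an estimated correlation), the glycolysis list 10 of 33 lower and 1 higher (15 and 3 adjusted over the list alone, camera adjusted p = 0.000163, adjusted p = 0.175 with an estimated correlation) and the mitochondrially encoded list 4 of 12 lower (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.109 with an estimated correlation). Kit, a growth factor receptor of melanocytes, was at 0.259 CPM in M1 and 1.75 CPM in M2, a change of −2.70 ± 0.39. The test called 2512 genes, 1418 higher and 1094 lower, of which 786 and 284 changed at least 2-fold. The split by direction depended on the settings, with 1313 higher and 629 lower with no filter and 1291 and 1184 by upper-quartile factors. It was 1060 and 626 without M1 replicate 1. Without M0 replicate 1 the test called 7233, including 2511 of the 2512. In that fit 34 cell cycle genes were lower and 2 higher, 16 melanocyte genes lower and 3 higher, and 22 glycolysis genes lower and 4 higher. It had 12 mesenchymal genes higher and 5 lower, and 14 of 19 death genes higher and 2 lower. It also had 7 immediate early genes higher and 4 lower, 6 mitochondrially encoded genes lower and 2 higher, and 5 of the IL-4 and STAT6 list higher and 1 lower (camera adjusted p = 0.0596).

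TAM differed in the same direction from each of M0, M1 and M2 in 4176 genes, 1974 higher and 2202 lower. Without M0 replicate 1 the number was 7549, with 7493 of them among the 14591 genes tested with all libraries, and 4152 of the 4176 were called again. Cholesterol, cell cycle and stress-response genes such as Dhcr7, Aurkb and Ppp1r15a belonged to this set. With all 12 libraries, every camera call given above without an estimated-correlation p also passed with an estimated correlation. Of these, 4 did not without M0 replicate 1. They were the cell cycle lists in M1 versus M0 and M1 versus M2 (adjusted p = 0.137 and 0.189 with an estimated correlation), the mitochondrially encoded genes in M1 versus M0 (0.257) and the NF-kB and inflammatory list in TAM versus M2 (0.0652).

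The M1 and TAM responses against M0 overlapped. Among 14591 genes, 816 were higher in both and 1321 lower in both, against 414 and 536 for independent lists, and 377 moved in opposite directions. Across genes, which are not independent replicates, their log2 changes correlated at r = 0.348 (rho = 0.527), M2 and TAM at 0.369 (rho = 0.433), and M1 and M2 at 0.33 (rho = 0.579). Comparisons with the same M0 libraries correlate with no effect at all, at a mean r of 0.836 for M1 and TAM in 20 simulations that kept the M0 libraries as deposited and 0.5 in simulations with drawn M0 libraries. The covariance of M1 and TAM was 0.487 against 0.0853 in the simulations that kept the M0 libraries, a difference of 0.402, and the differences were 0.0876 for M2 and TAM and 0.0899 for M1 and M2. The covariances without M0 replicate 1 were 0.438, 0.109 and 0.129 in the same order. A control divided into M0 replicate 2 for 1 response and M0 replicate 3 for the other, a test added after the data had been seen, shares no library and gave 0.412 and 0.445 in the 2 arrangements for M1 and TAM, 0.0803 and 0.0669 for M2 and TAM, and 0.0752 and 0.122 for M1 and M2. The correlations were then r = 0.274 and 0.3, 0.147 and 0.131, and 0.128 and 0.196. Counts of shared genes were not divided in this way, so part of their excess over independent lists may come from the shared controls.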

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

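Leaving M0 replicate 1 out of comparisons that do not use M0, and the offsets for exon length, were chosen after the data had been seen. The test against a fold of 1.5 asks for larger changes and called 1052 genes in M1 versus M0, 3346 in TAM versus M0, 2681 in TAM versus M1, 2744 in TAM versus M2 and 856 in M1 versus M2. Fitting only the libraries compared, where each spread rests on 6 libraries and M0 replicate 1 enters only the comparisons with M0, called 1282, 4619, 10301, 10182 and 6952. DESeq2 called 4 genes in M2 versus M0. The other settings stayed within 1.5 times of each total, though not always of the counts per direction. Among them, the offsets for exon length gave 4435 genes in M1 versus M0, 0 in M2 versus M0 and 8053 in TAM versus M0. The replicate number as a block gave 3156, 0, 7071, 5988, 6040 and 2172 genes in the 6 comparisons in the order of the report and 3976 in TAM against each other group. No scaling moved the median of all genes by over 0.1, but each method assumes that most genes do not change. Their closeness therefore says nothing about a shift shared by all genes.

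Leaving out 1 library at a time gave 2287 to 7056 genes in M1 versus M0, 0 to 51 in M2 versus M0, 6107 to 9983 in TAM versus M0, 5176 to 10489 in TAM versus M1, 5205 to 10407 in TAM versus M2, 1686 to 7233 in M1 versus M2 and 3348 to 7549 in TAM against each other group, each highest value being without M0 replicate 1. In M1 versus M0 the count was 2287 without M1 replicate 1 and 2351 without M1 replicate 3. No other library left out moved a total by over 1.5 times, but counts of 1 direction moved further. In M1 versus M0 the lower genes went from 1967 to 1115 without M1 replicate 2. In M1 versus M2 they went from 1094 to 626 without M1 replicate 1.

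Of the numbers of lists past camera, the estimated correlation gave 0 in M2 versus M0 and 8 in TAM versus M0. Fry gave 1 in M2 versus M0 and 20 in each of TAM versus M1 and TAM versus M2. In M1 versus M2 camera called 14 lists, 10 of them higher. With the replicate number as a block it called 12, 8 of them higher, as it did without M1 replicate 3, M2 replicate 2 or M2 replicate 3. With a library left out, M2 versus M0 gave 1 to 13 lists, 13 without M0 replicate 1, 4 without M0 replicate 2 or M2 replicate 1 and 1 without M0 replicate 3, where the STAT3 list was lost (adjusted p = 0.0944). Of 1386 alternatives for 132 list medians 1298 kept the direction and the side of the threshold, 39 lost a call, 42 gained one and 7 had a call with a median of another sign than with all libraries. Of these 7, 5 were in M2 versus M0 without M0 replicate 1, where the median became 0.126 for MHC class I (range over libraries left out −0.321 to 0.126), 0.061 for checkpoint (−0.088 to 0.061), 0.0979 for NF-kB (0 with all libraries, −0.102 to 0.0979), 0.0548 for stress response (−0.25 to 0.0548) and 0.0643 for oxidative stress genes (−0.369 to 0.0643). The direction given by camera was up in both fits for the checkpoint and NF-kB lists. The others were the immediate early genes in M1 versus M2, at −0.0192 without M1 replicate 3 and −0.0175 without M2 replicate 1 (up to 0.212). Among 1937 alternatives for 149 named genes 1912 kept direction and side of the threshold, 5 lost a call, all of them Irf1 in TAM versus M0, and 19 gained one. Tyrp1 in M2 versus M0 turned to −0.148 without M0 replicate 1, in a range up to 0.124. Irf1 in TAM versus M0 also missed the threshold without a filter (adjusted p = 0.0558) and with the replicate number as a block (adjusted p = 0.0509), and Cd68 in M1 versus M0 passed with limma-voom (adjusted p = 0.048) and without M0 replicate 1 (adjusted p = 0.00338). The cause was not tested for any of these.

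Similarity ranged with a library left out from 0.332 to 0.431 for M1 and TAM, 0.315 to 0.503 for M2 and TAM and 0.284 to 0.457 for M1 and M2, and among genes called in either it was 0.437 for M2 and TAM. With only M0 replicate 1 and 1 other M0 library left the shared noise is larger by construction. With the replicate number as a block it was 0.345, 0.367 and 0.324.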

Other observations

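The 3 tests on M0 replicate 1, the test of the sterol list in TAM versus M2 as a test of the M0 libraries and the test on IL-4 targets were chosen after the results they bear on were seen, as was the rule that a median near 0 over members moving both ways leaves a test undecided.

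Several genes near absence in M0 were among the largest rises in TAM versus M0. Cox6a2 had 904 counts in TAM and 1 in M0, a ratio of 838 with a 95% counting interval from 150 to 33100. Akr1b7, an aldo-keto reductase, had 1237 against 3 (382, 130 to 1860), Soat2, which esterifies cholesterol, 726 against 2 (336, 92.8 to 2780), Elfn2 386 against 1 (358, 63.8 to 14200) and Trim66 437 against 2 (202, 55.7 to 1680). In M1 versus M0, the class II gene H2-Aa was at least 79.4-fold higher, the lysosomal protease gene Ctss at least 26.5-fold and Nos2, encoding inducible nitric oxide synthase, at least 25.8-fold. Hsp90b1 and Canx, chaperones of the endoplasmic reticulum, were not called in TAM versus M2 (adjusted p = 0.987 and 0.561), whereas Hspa5 and Dnajb9 rose by 1.32 ± 0.08 and 1.91 ± 0.24 and Sdf2l1 and Pdia4 changed by −1.31 ± 0.20 and −1.19 ± 0.09.

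M0 replicate 1 stood apart from the other M0 libraries. A library of the M1 or TAM group in its place is argued against, since over genes that differed at least 4-fold between groups it lay 0 of the way from the M2 mean to the M1 mean (462 genes) and 0.02 of the way to the TAM mean (773 genes). For RNA of macrophages, the macrophage markers summed to 8.08 CPM in it without TMM scaling, within the 3.94 to 8.43 CPM of the other libraries. Its TMM factor of 0.924 was the lowest, so TMM scaling would raise its sum relative to the others. Its place within this range may not hold after scaling. The upper end came from the M1 libraries, at 8.01 to 8.43 CPM, whereas M0 replicates 2 and 3 held 6.16 and 5.27 CPM. Coro1a, Lyz2 and Fcer1g, all near the detection limit, were higher in it than in any other library, at 1.85, 1.24 and 1.13 CPM. The range over all groups therefore left this explanation undecided for M0 replicate 1. Its log2 difference from the other M0 libraries fell with exon length, with a rho of −0.458 across 14580 genes against −0.157 to 0.129 for the other libraries, and medians of 0.62 in the 1458 genes of at most 1087 bp and −0.99 in the 1458 of at least 9486 bp, so a loss of counts from long transcripts, as from degraded RNA or a different library preparation, is a candidate explanation. GC content gave a rho of 0.466 and was not separated from length, and no biological explanation was tested.

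Lower sterol synthesis genes and higher stress-response genes in TAM did not depend on M0, since their medians in TAM versus M2 were −1.96 and 1.65, and −1.94 and 1.72 once the trend of the changes with exon length and GC content was removed. For a hypothesis of amino acid shortage, the cytoplasmic tRNA synthetases reached the bound set beforehand, with 13 of 18 higher in TAM versus M2 (median 0.599), such as Lars at 1.42 ± 0.11. Kars, Mars and Qars were lower, at −0.67 ± 0.15, −0.80 ± 0.14 and −0.79 ± 0.12. In TAM versus M1, for which no bound was set, only 6 were higher and 3 lower (median 0.242). M1 versus M2 had 6 higher and 0 lower (median 0.358), so part of the rise was also seen in M1. Any activation of ATF4 would also raise the list, so the explanation stays a candidate. Sterol surplus acting through LXR and protein load in the endoplasmic reticulum stayed open. Their medians of 0.0136 (4 of 6 LXR targets tested, Mylip −0.82 and Smpdl3a 0.49) and −0.202 (15 chaperones, 4 higher and 5 lower) met the bounds set beforehand against them, but the members moved both ways. The chaperones Hspa5, Hsp90b1, Pdia4, Dnajb9, Sdf2l1 and Creld2 are also in the stress-response list, so the chaperone test was not independent of the pattern. Because TAM macrophages were given 75% tumour-conditioned medium, nutrients spent by tumour cells and factors made by macrophages could each contribute and the design does not separate them.

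The genes called in M2 versus M0 without M0 replicate 1 numbered 51. IL-4 carried into the melanoma cultures is not excluded. Among 7 tested members of the IL-4 and STAT6 list edgeR called 0, which met the bound set against this explanation. However, 1 was higher adjusted over the list alone and 1 at an unadjusted p under 0.05, Socs1, at 1.30 ± 0.32 (adjusted p = 0.0589). The test was therefore left undecided, and other cytokines may raise Socs1 as well. No other biological explanation was tested. The 5 libraries make 10 splits, too few for a share under 0.05, and the highest other split called 3 genes.

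For the comparisons with 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 3744 genes in M1 versus M0 and the highest other 1, while for 7372 in TAM versus M0, 6279 in TAM versus M1, 6309 in TAM versus M2 and 2512 in M1 versus M2 the highest other called 0 with edgeR. In M2 versus M0 all 10 splits called 0. For gene lists the real and highest other numbers were 14 and 11 in M1 versus M0, 2 and 4 in M2 versus M0, 14 and 12 in TAM versus M0, 13 and 14 in TAM versus M1, 13 and 13 in TAM versus M2, and 14 and 13 in M1 versus M2, and as many lists as in the real split were called in 9 splits for M2 versus M0 and in 4 each for TAM versus M1 and TAM versus M2. Numbers of lists past camera therefore carry little weight by themselves. For the 4176 genes that differed in TAM from each other group, 1 of 100 splits of the 12 libraries, the real one, gave as many. The highest other gave 3528, another with the TAM libraries together 3501, 1 with the M1 libraries together 533 and the other 96 gave 0. Mixing libraries of unlike groups widens the shared spread, so most other splits could hardly give any gene. The share of 1 in 100 therefore shows mainly that the TAM libraries were alike. It excludes neither chance nor differences between cultures.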
